A study of Homo sapiens with 4 samples.

How the data were processed

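RNA of LNCaP cells transfected with 50 nM of a miR-135a mimic or negative control was compared on 4 Agilent whole human genome arrays of 60-base probes, 2 at 24 h (replicates 1 and 2) and 2 at 48 h (replicates 3 and 4). Each array held both RNAs in different dyes, with dyes swapped within each time per the labels. The authors scanned the arrays in both channels and extracted them with Agilent Feature Extraction (10.7.3.1 per the file headers, while their processing notes name 10.5 and limma with no version). Per the file headers the files hold intensity per spot (mean signal and median local background per channel, and processed signals that the software background-subtracted and dye-normalized). They also hold, per the file headers, the log10 ratio of processed red (Cy5) over green (Cy3), which served only to read the authors' processed values. The deposited table of those holds log2 ratios that the authors normalized within each array, with the background method unstated. Read by spot order, each of its columns correlated with the scanner's log2 ratio of the same array (r = 0.957 to 0.969, slope 0.790 to 0.830), so scale and direction (Cy5 over Cy3) follow from the values, while the exact centring stays unknown (column medians 0.0092, 0.0150, 0.0121 and 0.0157). Spike-in ratios per the file headers had slopes of 0.799, 0.712, 0.709 and 0.705 against their known log ratios, so large ratios are compressed.

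Signals were read with R 4.3.3, limma 3.58.1 and the data.table package (1.17.8). Background was corrected with normexp (offset 50) over 44495 spots, and each array was normalized with loess, with control spots at weight 0. The 43118 other spots were averaged to 34127 probes. Spots marked as uneven by the scanner were kept, since leaving them out was listed as an alternative, and 0 spots were saturated. A probe was kept if well above background on both arrays of at least 1 of the 4 sets (labelled mimic or control, 24 h or 48 h), which left 18008 probes. Names came through the accession in the file (25422 probes), a current symbol (1163) or an older one (382) of the RefSeq table for GRCh38.p14, which served for names only, and 7160 probes kept the file's name. Positions are those of the files (hg19). The brightest probe stood for each gene, which gave 14626 genes. At 24 h 14448 genes, and at 48 h 14229, were well above background in both RNAs on at least 1 array; ROCK2 at 48 h was the only named gene that was not.

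Log2 ratios of red over green were fitted with limma's lmFit and eBayes, with a mimic effect at 24 h, one at 48 h and 1 dye term shared by all arrays, which left 1 residual degree of freedom and a prior of 10.2. The difference between times is a contrast of this fit. The mean over both times was fitted to 1 value per time, with a prior of 18.7 degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested, at 0.05. Over 19 gene lists, limma's camera with a preset correlation of 0.01 was run per time and on the difference, and again with an estimated correlation, and fry on the same fit. With an estimated correlation, camera rests on the 1 residual degree of freedom, so hardly any list could pass, whatever its correlation. Fry rests on it too, so its p-values depend on 1 residual value per list and do not rank the lists. The lists given here are reported miR-135 targets, androgen response, G2/M and mitosis, DNA replication and S phase, p53 targets and apoptosis, interferon response, cholesterol and fatty acid synthesis, unfolded protein and amino acid stress, heat shock, hypoxia response, epithelial adhesion, mesenchymal and invasion genes, WNT and beta-catenin targets, TGF-beta and BMP signalling, oxidative phosphorylation and ERRalpha targets, miRNA pathway, neuroendocrine markers, and markers of other cell types. 1 further list and 2 genes are not reported here. Lists, tests, alternatives and the rule for naming genes were fixed before the data were examined, except where stated.

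The rule named, per time, the 12 genes with the largest rise and the 12 with the largest fall among those that passed, changed the same way on both arrays and had a gene symbol, the 5 largest differences between times each way, up to 4 members per list with the smallest adjusted p, and ROCK1, ROCK2 and ESRRA. Genes named with the probes over 60% GC left out, and those marked so in the text, were chosen after their values were seen.

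The miR-135a seed match was searched in the sequence of each probe, since sequences of 3′ untranslated regions were not at hand. Probes read in the direction of the mRNA: 2617 of 34127 held the polyadenylation signal AATAAA and 1298 its reverse complement. Genes with and without the match were compared with 100000 permutations of the gene labels, and the match was ranked among heptamers found in at least 20 genes. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

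The fit was tested on simulated data with the spread of these arrays, in 20 draws of 14626 genes with 50 genes changed at each size. At 24 h a change of 0.3 was recovered in 57% of genes (median over draws) and one of 0.6 in 100%; at 48 h the shares were 58% and 100%, in the difference 14% and 94%, and in the mean over both times 94% and 100%. Of the genes called, the median share that had not changed was 9.49% at 24 h, 13.1% at 48 h, 12.4% in the difference and 8.76% in the mean, with up to 26.0% in 1 draw. Far fewer genes changed here than the 5784, 4535 and 4704 that passed at 24 h, at 48 h and in the difference. The adjustment was therefore stricter, and these shares do not give the rates in the real data. Noise and dye effect followed the fit's own model, so the draws cannot show faults of that model. For the mean, each simulated gene changed alike at both times, with noise between arrays only. The shares for the mean therefore do not describe the real test, whose spread includes the difference between times. The standard error of ROCK1 was 0.07 at 24 h and 0.13 in the mean, although its changes at 24 h and 48 h were close (0.62 and 0.59). The larger value thus comes mostly from other genes, through the prior of 18.7 degrees of freedom. Among the lists, only the one with a shift of 0.3 put in passed camera (adjusted p = 1.5e-57). Errors were drawn independently for each gene, so this cannot show how camera with its preset correlation behaves on correlated genes.

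Alternatives covered the background correction (none, the scanner's processed signals, offset 10), normalization (median centring, Aquantile after loess), filter (none, or well above background in all channels), probe choice (average), spots marked as uneven left out, an intensity trend with robust prior, the deposited value table, no dye term, 4 arrays as 4 replicates, and each replicate left out in turn. Added after the data were seen were the probes over 60% GC left out and a seed test within 10 classes of probe GC. The rank among heptamers with as many G and C bases was not planned either. Control spots were left out of every test.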

Results

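Messenger RNA was measured in LNCaP cells, an established line of human prostate cancer cells that responds to androgen, after lipid transfection with a mimic of the microRNA hsa-miR-135a or with a negative control, at 50 nM. The purpose stated for the series is to find target genes of this microRNA. RNA was compared at 24 h and at 48 h on 4 Agilent 2-colour arrays of 60-base probes, each holding RNA labelled mimic in one dye and RNA labelled control in the other. The arrays form 1 dye-swapped pair per time: RNA labelled mimic carried Cy3 on replicates 1 (24 h) and 3 (48 h), and Cy5 on replicates 2 (24 h) and 4 (48 h). All 4 lay on 1 slide and were read in 1 scan. Per channel, 53.4% to 60.3% of 43118 spots were well above background, and the median signal was 2.74 to 5.95 times the background. After a filter on dim probes 14626 genes were tested, and the number of arrays limits the precision. Log ratios turned to labelled mimic over control correlated between the 2 arrays of a time (r = 0.779 at 24 h and 0.664 at 48 h, over 21397 spots) more than between arrays of different times (0.060 to 0.450). The labels do not say whether the 2 arrays of a time hold the same RNA extracts. If they do, the spread between arrays on which p-values per time rest is technical. That spread leaves out any disagreement of a time's 2 arrays that recurs with the dyes at the other time, which the fit counts as dye. It also rests largely on other genes through the prior. With no dye term 3271 genes passed at 24 h in place of 5784, and 1756 at 48 h in place of 4535.

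Genes whose probe held a match to the miR-135a seed, the part of a microRNA that pairs with its targets, were higher in the RNA labelled mimic at both times. The 64 genes with the 7-base match AAGCCAT lay 0.15 ± 0.03 (SE across genes) above the others on the log2 scale at 24 h and 0.13 ± 0.02 at 48 h (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give, and 3e-05). The 239 genes with the 6-base match AGCCAT lay 0.083 and 0.068 above the others (permutation p = 1e-05 and 2e-05), and 15 genes with the 8-base match AAGCCATA lay 0.16 and 0.21 above. Each array gave the 7-base shift with the same sign (0.14, 0.16, 0.14 and 0.12 for replicates 1 to 4). The reverse complement ATGGCTT gave 0.043 (permutation p = 0.116) and 0.015 (permutation p = 0.495), and the seed match of the opposite arm, TCCCTAT, gave 0.025 ± 0.043 and 0.041 ± 0.048 over 34 genes. Among all 11566 heptamers, AAGCCAT ranked 58 at 24 h and 11 at 48 h by its shift over the standard error. Among the 3652 with as many G and C bases, a comparison that was not planned, it ranked first at each time. These tests run across genes, which are not independent replicates, and search only the 60 bases of each probe. MicroRNAs are known to lower RNAs that match their seed, so this direction opposes the one the labels and the purpose of the series give. All signed values keep the direction of the labels ("labelled mimic"); an exchange of both RNAs on all 4 arrays would turn each sign and leave each size and test as it is.

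**Figure D1:**
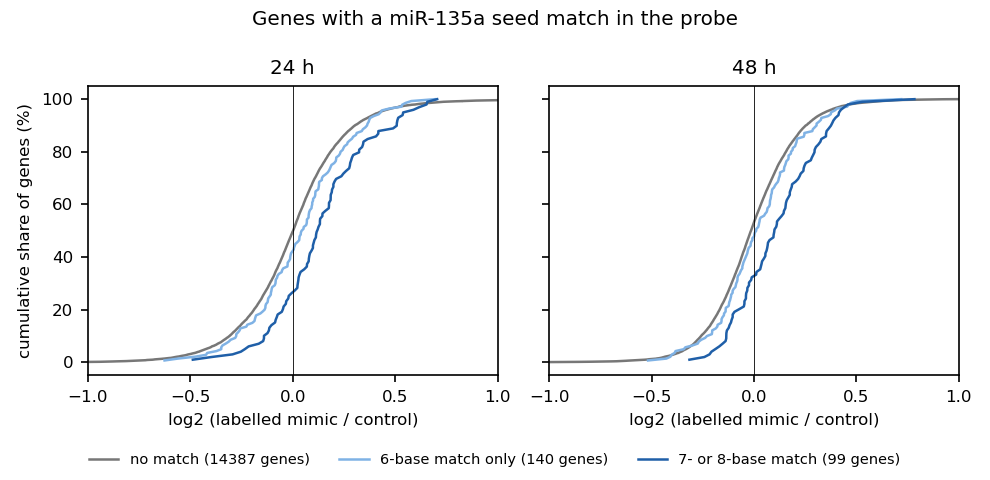
Cumulative share of genes (%) against the log2 ratio of RNA labelled mimic over control at 24 h (left) and 48 h (right), for genes with a 7- or 8-base match to the miR-135a seed in the probe, with the 6-base match only, and with none. The curves of genes with a match lie to the right of the curve of genes without one over most of the range at both times.

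At 24 h the RNA labelled mimic held less S1PR3, a receptor for sphingosine 1-phosphate, with a log2 ratio of -2.21 ± 0.07 (limma adjusted p = 2.9e-08). It was the mean of n = 2 arrays (-2.03 and -2.40), and another probe gave -0.81. Here and below, ± gives the SE of the fit to all 4 arrays, drawn towards that of other genes by the prior. A gene has the same SE at 24 h and 48 h, which does not show how well the 2 arrays of a time agree. Genes of flagella and motile cilia also fell: SPEF1 at -1.62 ± 0.07, ROPN1L at -1.19 ± 0.11 (a spot on 1 array was marked as uneven by the scanner) and RSPH1, a radial spoke protein, at -1.14 ± 0.07. DICER1, which cuts microRNA precursors, fell (-1.18 ± 0.07), as did RRAGC, a GTPase of amino acid sensing (-1.17), the transcription factor SOX8 (-1.22) and the small GTPase RAB12 (-1.32 ± 0.17). STXBP5L (-1.30; 2 other probes -0.47 and -0.36) and the copper transporter ATP7A (-1.28; 3 other probes between -0.24 and 0.03) fell by more in the brightest probe than in the others. Histone H4C3 rose by 1.49 ± 0.07, BPNT1, a nucleotidase, by 1.43 (another probe 0.99), the mitochondrially encoded oxidase subunit COX1 by 1.41, the zinc finger protein ZNF652 by 1.30 and the RNA-binding protein TAF15 by 1.27. The probe of S1PR3 lies on chromosome 9 at 91619814 to 91619873 (hg19), that of DICER1 on chromosome 14 at 95552615 to 95552674, and that of H4C3 on chromosome 6 at 26104468 to 26104527.

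The changes of 3 genes at 24 h rested on 1 array. EGF, a growth factor, was at 1.53 ± 0.26 (2.80 on replicate 1 and 0.27 on replicate 2, with an uneven spot on 1 array; adjusted p = 0.16 without replicate 1). SPRYD4 was at -2.94 ± 0.61 (-5.81 and -0.07; adjusted p = 0.77 without replicate 1), and with the scanner's processed signals it was at -0.04 (adjusted p = 0.66). USP6NL was at -1.95 ± 0.37 (-0.40 and -3.50, with an uneven spot on 1 array; adjusted p = 0.077 without replicate 2).

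A block of 45 genes that at least doubled at 24 h and lay below 0 at 48 h included 28S ribosomal RNA (RNA28SN5, 1.31 ± 0.08 at 24 h and -0.30 ± 0.08 at 48 h), whose 3 other probes gave 1.15 to 1.16 at 24 h. It held 5 of the other genes that the rule for naming picks at 24 h: the nuclear lamina protein LMNB1 at 1.33 ± 0.13 (0.76 and 1.90 on replicates 1 and 2), NKX2-5 at 1.29, DUX4 at 1.29, VPS9D1 at 1.25 and PRR36 at 1.24. Other probes of these genes did not share the change: LMNB1 0.01, DUX4 between -0.07 and 0.08, VPS9D1 0.07 and PRR36 -0.02, with none for NKX2-5. The probes of the block had a median GC content of 75%, against 43.3% for all genes. Of the 56 genes at least doubled at 24 h, 31 had a probe over 60% GC, as did 263 of all genes tested. With those probes left out (a choice made after the values were seen), H4C13, LBX1 and FOXP4 took the places of DUX4, VPS9D1 and PRR36, at 1.24, 1.22 and 1.19; LBX1 and FOXP4 belong to the block too (other probes of H4C13 and FOXP4 gave -0.07 and 0.04).

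**Figure D2:**
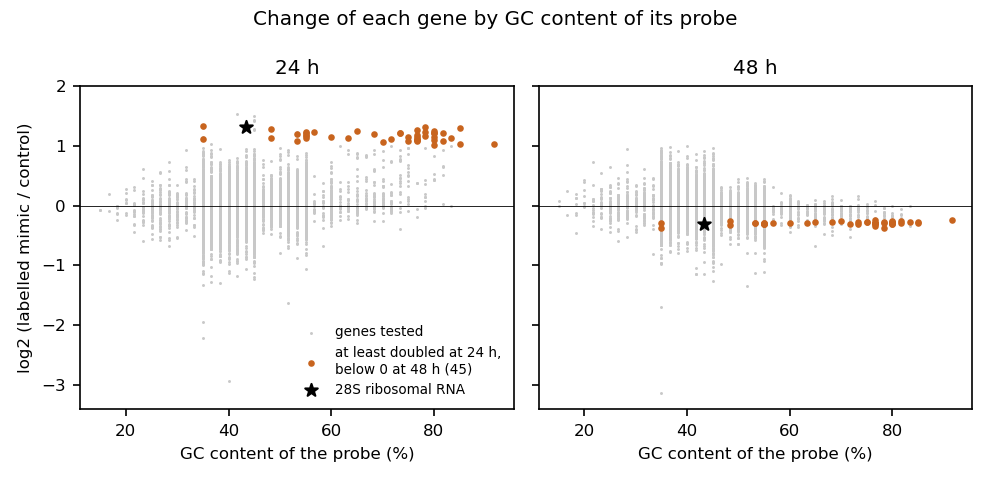
Log2 ratio of RNA labelled mimic over control against the GC content of the probe (%) at 24 h (left) and 48 h (right), for genes tested (grey), the 45 genes at least doubled at 24 h and below 0 at 48 h (orange) and 28S ribosomal RNA (star). The 45 genes lie between 1.01 and 1.33 at 24 h, with a median of -0.29 at 48 h.

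In all, 5784 of 14626 genes passed at 24 h in limma (2837 higher and 2947 lower in RNA labelled mimic), of which 56 at least doubled and 21 at least halved. Of 1318 genes that passed and had another probe above background, 410 had one with the opposite sign. With median centring of each array in place of loess, 87 genes passed (10 higher, 77 lower) and the median of all genes moved to -0.10. Without replicate 2, 1180 passed.

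Genes of cell division were higher in RNA labelled mimic at 24 h, and targets of p53 lower. Of 25 genes of G2/M and mitosis, 23 rose and 0 fell (24 and 0 adjusted over the list alone; median 0.45), among them BUB1B, a spindle checkpoint kinase, at 0.91 ± 0.08, the mitotic kinesin KIF23 at 0.81 and the cyclin-dependent kinase CDK1 at 0.60. Of 28 genes of DNA replication and S phase, 22 rose and 1 fell (23 and 1 adjusted over the list alone; median 0.48), among them the replicative helicase subunits MCM5 at 1.16 ± 0.08 and MCM2 at 0.79. UHRF1, which keeps DNA methylation through replication, was the one that fell (-0.75). Of 19 targets of p53 and apoptosis genes, 1 rose and 14 fell (2 and 15 adjusted over the list alone; median -0.30): the growth inhibitor SESN1 at -1.02 ± 0.08, the death receptor FAS at -0.96 and the cell death gene BBC3 at -0.82. BAX was the one that rose (0.44). UHRF1 and BAX were chosen after their values were seen. The 3 lists passed camera with its preset correlation (adjusted p = 6.2e-11, 2.8e-10 and 1.2e-05), each at adjusted p = 0.68 with an estimated correlation. The latter form rests on 1 residual degree of freedom, so hardly any list could pass it. In camera the p53 list went from an unadjusted p of 1.8e-06 to 0.12, with an estimated correlation (-0.053) below the preset one.

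Of 29 androgen response genes, 17 rose and 5 fell at 24 h (18 and 5 adjusted over the list alone; median 0.28; adjusted p = 0.0012): EAF2 was at 0.60, the fatty acid enzyme ACSL3 at 0.71, and the cation channel TRPM8 at -0.57. Of 22 genes of unfolded protein and amino acid stress, 7 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.14; adjusted p = 0.031), among them XBP1 at 0.53 and VLDLR at 0.52. Of 13 genes of the miRNA pathway, 0 rose and 7 fell (0 and 7 adjusted over the list alone; median -0.22; adjusted p = 0.036): DICER1 as above, AGO3 at -0.30 (another probe 0.19), AGO4 at -0.33 and TNRC6B at -0.28. Without replicate 1, XBP1 (0.36), AGO3 (-0.30) and TNRC6B (-0.23) did not pass, and without replicate 2, ACSL3 (0.43), VLDLR (0.33), AGO3 (-0.31), TNRC6B (-0.32) and AGO4 (-0.19, adjusted p = 0.49). TNRC6B did not pass without replicate 3 or 4 either (-0.28, the same fit at 24 h, which keeps both arrays of that time). The stress list did not pass without replicate 1, without replicate 3 or 4 (the same fit at 24 h), with processed signals (camera adjusted p = 0.11) or with median centring (0.81). Nor did the miRNA pathway without replicate 1 (adjusted p = 0.14) or with processed signals (0.10), and the androgen response with median centring (0.12). Each of these 3 lists also had adjusted p = 0.68 with an estimated correlation, with which 0 of 19 lists passed and 0 had an unadjusted p under 0.05. With 1 residual degree of freedom in that form, this tells little about correlation within the lists. Limma's fry, which asks whether a list's genes move one way, called only the miRNA pathway (adjusted p = 0.0034). Fry rests on the same 1 residual degree of freedom, so this call does not single that list out. The G2/M list, with a median of 0.45, had a fry adjusted p of 0.16.

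Of 21 genes reported as miR-135 targets before, 7 rose and 2 fell at 24 h (8 and 2 adjusted over the list alone, median 0.12), against 2837 and 2947 of all 14626 genes. The list did not pass (camera adjusted p = 0.054, and 0.68 with an estimated correlation). ROCK1, a kinase of the actin cytoskeleton, was at 0.62 ± 0.07 (0.37 and 0.87 on replicates 1 and 2, and another probe 0.15). Its limma adjusted p was 9.2e-05, and up to 0.43 over 17 alternatives, of which 15 kept the call. Without replicate 2 it was at 0.37 and did not pass. ESRRA, a nuclear receptor of energy metabolism, was at 0.60 ± 0.07 (another probe 0.95). Of 17 alternatives 16 kept its call, with a limma adjusted p up to 0.80. ROCK2, with a value of 0.18 ± 0.07, did not pass (adjusted p = 0.067).

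The other lists did not pass at 24 h (camera adjusted p = 0.12 to 0.68). Their counts are to be read beside the 2837 genes that rose and 2947 that fell among all 14626. Among 27 interferon response genes 2 rose and 9 fell (3 and 10 adjusted over the list alone), with OASL at -0.77, IFIT2 at -0.50 and IFIT1 at -0.51. Among 28 genes of cholesterol and fatty acid synthesis 6 rose and 7 fell, as over the list alone, with HMGCS1 at -0.68 and SCD at -0.59. Of 10 heat shock genes 5 rose and 2 fell, as over the list alone, with BAG3 at 0.62 and HSPA8 at 0.51 (down to 0.39 and 0.11 over the alternatives). Of 19 hypoxia genes 6 rose and 3 fell, as over the list alone, with NDRG1 at 0.46. Of 20 epithelial adhesion genes 3 rose and 4 fell, as over the list alone, with CTNNB1 at -0.59 (another probe 0.06) and OCLN at -0.55. Of 25 genes of oxidative phosphorylation 5 rose and 1 fell, as over the list alone, with COX6C at 0.40 (down to 0.069 over the alternatives). In the smaller lists, 2 of 8 mesenchymal genes rose and 1 fell (VIM at -0.37), 3 of 7 WNT target genes rose and 2 fell (CCND1 at 0.53, BAMBI at -0.41), and 3 of 17 genes of TGF-beta and BMP signalling rose and 1 fell (SMAD3 at -0.26); adjusted over the list alone the counts were 2 and 1, 3 and 2, and 2 and 1. Of 4 neuroendocrine genes 1 fell (TUBB3 at -0.54; 2 adjusted over the list alone). Of 5 markers of other cell types 1 rose and 2 fell, as over the list alone: CD68, of macrophages, was at 0.31, ACTA2, of smooth muscle, at -0.80, and VWF, of endothelium, at -0.54. Without replicate 1, VIM (-0.26) and SMAD3 (-0.25) did not pass, and without replicate 2, IFIT1 (-0.41), BAG3 (0.39), COX6C (0.38), SMAD3 (-0.26) and CD68 (0.16, adjusted p = 0.60). SMAD3 did not pass without replicate 3 or 4 either (-0.26, the same fit at 24 h).

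**Figure D3:**
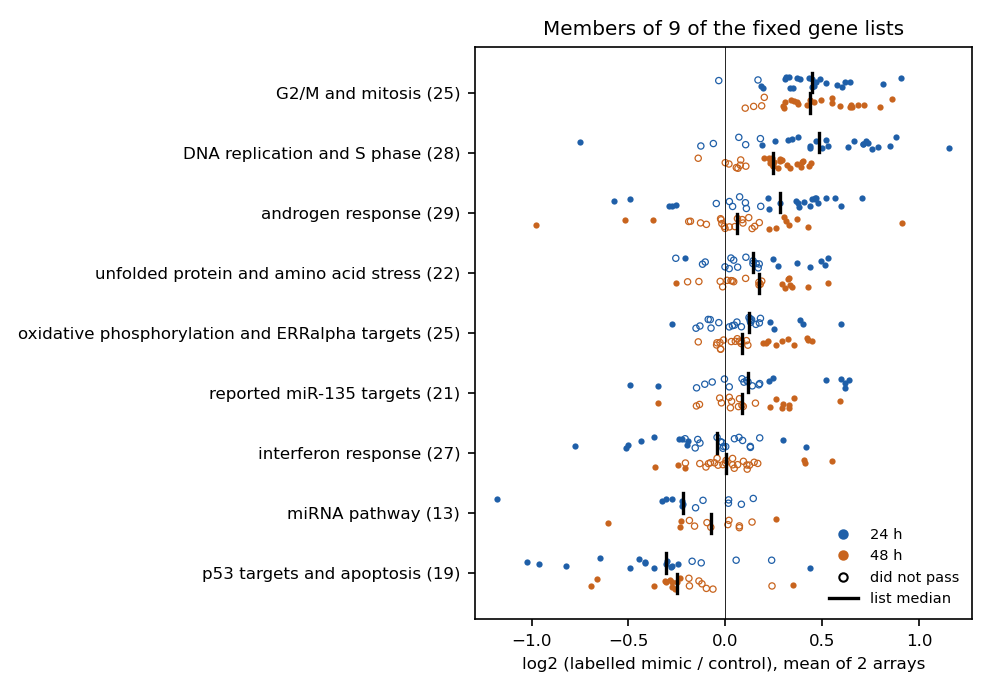
Log2 ratio of RNA labelled mimic over control for each tested member of 9 gene lists at 24 h (blue) and 48 h (orange); filled points passed, open points did not, bars are list medians, and the number tested stands after each name. The medians of the G2/M list are 0.45 at 24 h and 0.44 at 48 h, and those of the p53 list -0.30 and -0.25.

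At 48 h S1PR3 was lowest in RNA labelled mimic, at -3.14 ± 0.07 (n = 2 arrays, adjusted p = 6.1e-10; another probe -1.21). It was followed by TMEM65, at -1.70 ± 0.22, and by SPEF1 (-1.34 ± 0.07) and ROPN1L (-1.27 ± 0.11). GRIN3A, an NMDA receptor subunit, fell (-1.14 ± 0.07), as did the surface protein CD24 (-1.14), the nitric oxide synthase NOS3 (-1.13), RAB36 (-1.11), the secreted phospholipase PLA2G2A (-1.09), ACTA2 (-1.04), IQCK (-1.03) and CTXN1 (-0.98). The histone chaperone HIRA rose by 1.00 ± 0.10, SCML1 by 0.96, MED18, a Mediator subunit, by 0.96 (another probe 0.53) and AMTN by 0.94. Rises were also seen in MYNN (0.97; another probe 0.57), the signalling proteins GNB4 (0.92) and RIT1 (0.92), the prostaglandin dehydrogenase HPGD (0.91), the prostatic acid phosphatase ACP3 (0.91; another probe 0.22), ASPH (0.90; other probes 0.03 and 0.62), the mitotic kinesin KIF14 (0.89) and the potassium channel KCNMA1 (0.88; other probes -0.03 and 0.44). The probe of HIRA lies on chromosome 22 at 19318407 to 19318466, and that of TMEM65 on chromosome 8 at 125324261 to 125324320 (hg19).

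In limma 4535 genes passed at 48 h (2258 higher and 2277 lower), of which 0 at least doubled and 12 at least halved. Of 936 genes that passed and had another probe, 134 had one with the opposite sign. With median centring 4 genes passed (0 higher, 4 lower; 307 at an unadjusted p under 0.05), and without replicate 3 or 4, 896 or 341.

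At 48 h genes of dividing cells were again higher. Of 25 G2/M genes 21 rose and 0 fell (23 and 0 adjusted over the list alone; median 0.44), with CENPE at 0.86 ± 0.07, CENPF at 0.80 and CDK1 at 0.71. Of 28 S phase genes 20 rose and 0 fell, as over the list alone (median 0.25), with the replication factor RFC4 at 0.44. Of 19 p53 target and apoptosis genes 1 rose and 11 fell (1 and 13 adjusted over the list alone; median -0.25), with the cyclin-dependent kinase inhibitor CDKN1A at -0.70 (-0.38 and -1.01 on replicates 3 and 4) and FAS at -0.66. The gene that rose was PMAIP1, a promoter of apoptosis, at 0.35. RFC4 and PMAIP1 did not pass without replicate 3 (0.39 and 0.37) or replicate 4 (0.49 and 0.32), nor CDKN1A without replicate 4 (adjusted p = 0.29). Camera gave adjusted p = 5.3e-15, 6.3e-07 and 0.00045, each 0.92 with an estimated correlation (on 1 residual degree of freedom, as at 24 h).

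Of 25 genes of oxidative phosphorylation and ERRalpha targets, 10 rose and 0 fell at 48 h, as over the list alone (median 0.084; adjusted p = 0.0058), with the electron carrier CYCS at 0.45, ACADM at 0.42 and ESRRA at 0.36 ± 0.07 (another probe 0.22). Of 22 stress genes 8 rose and 1 fell (12 and 2 adjusted over the list alone; median 0.17; adjusted p = 0.0085), with VLDLR at 0.53 and ASNS at 0.43. Of 21 reported miR-135 targets 8 rose and 1 fell, as over the list alone (median 0.086, camera adjusted p = 0.026). ROCK1 was at 0.59 ± 0.07 (limma adjusted p = 0.00028, a call kept in 15 of 17 alternatives, and another probe 0.33), SIAH1 at 0.33 and KLF8 at -0.35. Without replicate 4, ROCK1 was at 0.49, VLDLR at 0.44, SIAH1 at 0.20 (adjusted p = 0.70), KLF8 at -0.29 (adjusted p = 0.51), ESRRA at 0.46, CYCS at 0.51, ACADM at 0.39 and ASNS at 0.51, and none of them passed. Of these, all but ROCK1 and VLDLR did not pass without replicate 3 either (SIAH1 0.46, KLF8 -0.41, ESRRA 0.25, CYCS 0.38, ACADM 0.46 and ASNS 0.34). None of the 3 lists passed without replicate 3 (adjusted p = 0.10, 0.17 and 0.15). ESRRA also stands in the list of oxidative phosphorylation. ROCK2 was at 0.07 (adjusted p = 0.46); the RNA labelled control was not well above background for ROCK2 on either array. Each of these 3 lists had adjusted p = 0.92 with an estimated correlation, with which 0 of 19 lists passed and 0 had an unadjusted p under 0.05. As at 24 h, that form had 1 residual degree of freedom and could hardly pass any list. Limma's fry called only the miRNA pathway (adjusted p = 0.033), again on 1 residual degree of freedom, which does not single that list out.

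The other lists did not pass at 48 h (camera adjusted p = 0.36 to 0.99). Their counts are to be read beside the 2258 genes that rose and 2277 that fell among all 14626. Of 29 androgen response genes 8 rose and 3 fell, as over the list alone, with HPGD at 0.91, MAF at -0.52 and TRPM8 at -0.98. Of 13 miRNA pathway genes 1 rose and 3 fell (1 and 4 adjusted over the list alone), with DICER1 at -0.61 and AGO2 at -0.23. Of 27 interferon genes 3 rose and 3 fell, as over the list alone, with IFIT2 at 0.41 and IFIT1 at 0.41. Of 28 lipid synthesis genes 8 rose and 4 fell (9 and 4 adjusted over the list alone), with ELOVL6 at 0.67 and SCD at 0.57. Of 10 heat shock genes 0 rose and 1 fell (HSPA1B at -0.56), as over the list alone, and of 19 hypoxia genes 1 rose (PDK1 at 0.25) and 1 fell (0 and 0 adjusted over the list alone). Of 20 epithelial genes 3 rose and 6 fell (3 and 7 adjusted over the list alone), with JUP at -0.36. Of 8 mesenchymal genes 1 rose (ITGB1 at 0.52) and 1 fell, and of 7 WNT target genes 1 rose (LEF1 at 0.37) and 1 fell (BAMBI at -0.41), as over each list alone. Of 17 genes of TGF-beta and BMP signalling 2 rose and 2 fell (0 and 1 adjusted over the list alone), with ID2 at -0.29. Of 4 neuroendocrine genes 1 fell (TUBB3 at -0.52), and of 5 markers of other cell types 1 rose (COL1A1 at 0.33) and 2 fell (ACTA2, and VWF at -0.53), as over each list alone. Neither without replicate 3 nor without replicate 4 did AGO2 (-0.29 and -0.17), IFIT2 (0.44 and 0.37), IFIT1 (0.48 and 0.34), PDK1 (0.30 and 0.21), JUP (-0.35 and -0.38), LEF1 (0.33 and 0.40), ID2 (-0.21 and -0.37) and COL1A1 (0.44 and 0.21, adjusted p = 0.67) pass. Nor did MAF (-0.47) and VWF (-0.47) without replicate 3, or SCD (0.50), HSPA1B (-0.44), ITGB1 (0.40), BAMBI (-0.33) and TUBB3 (-0.39) without replicate 4. PDK1 (0.25) and AGO2 (-0.23) did not pass without replicate 1 or 2 either (the same fit at 48 h, which keeps both arrays of that time).

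Between the times, the ratio of labelled mimic over control rose most for SPRYD4 (3.12, resting on replicate 1), RAB12 (1.94), USP6NL (1.82, resting on replicate 2), PRRG1 (1.43; its other probe moved from 0.08 to 0.10) and MAGOH (1.26), a core protein of the exon junction complex. It fell most for TMEM65 (-2.04, and -1.17 without replicate 2; -0.53 and 1.21 on replicates 1 and 2), LMNB1 (-1.70, and -1.13 without replicate 2), HINT3 (-1.64), RNA28SN5 (-1.61) and NKX2-5 (-1.61). The test of the difference passed for 4704 genes (2350 higher and 2354 lower at 48 h), and for 4 with median centring (465 at an unadjusted p under 0.05). Without replicate 4, 444 passed. Of the 19 lists only that of DNA replication and S phase shifted (median -0.26; camera adjusted p = 0.020, but 0.99 with an estimated correlation and 0.33 by fry), with MCM5 at 1.16 at 24 h and 0.02 at 48 h. Fry called only the miRNA pathway (adjusted p = 0.023), with the same limit as at each time. DICER1 (0.57, adjusted p = 0.0020) differed between the times. ROCK1 differed by -0.03 (adjusted p = 0.86).

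Over both times together, S1PR3 (log2 mean -2.68, adjusted p = 1.5e-08), SPEF1 (-1.48), ROPN1L (-1.23), RAB36 (-1.09), SOX8 (-1.08) and IQCK (-1.08) fell, and ZNF652 (1.04), SCML1 (0.96), ASPH (0.87) and KCNMA1 (0.87) rose. ROCK1 (0.61, adjusted p = 0.025), KIF23 (0.75) and CDK1 (0.66) rose, and FAS (-0.81), CDKN1A (-0.59) and DICER1 (-0.89) fell. This test takes each time's pair of arrays as 1 value (n = 2), so its spread includes the difference between times. It passed for 228 genes (115 higher, 113 lower), of which 226 had the same direction on all 4 arrays. With the sign at 48 h turned, 0 genes passed in limma (251 at an unadjusted p under 0.05, against 1645 with the sign as labelled). Without replicate 1, 2, 3 or 4, 93, 0, 22 or 519 genes passed (1374 at an unadjusted p under 0.05 without replicate 2), and in each case all 228 kept their direction. The kept direction was nearly fixed in advance, since 226 had 1 direction on all 4 arrays. With no filter on dim probes 0 passed (2383 at an unadjusted p under 0.05), and with an intensity trend and robust prior 2.

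Across genes, the changes at 24 h and 48 h correlated weakly (Pearson's r = 0.225, Spearman's rank correlation 0.146, 14626 genes, which are not independent replicates). Of 2159 genes that passed at both times, 758 rose at both and 771 fell at both, against 532.4 and 545.4 if the directions at the 2 times were independent among these genes; 358 and 272 changed direction, against 1081.2 in all. Without replicate 3, r was 0.132.

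**Figure D4:**
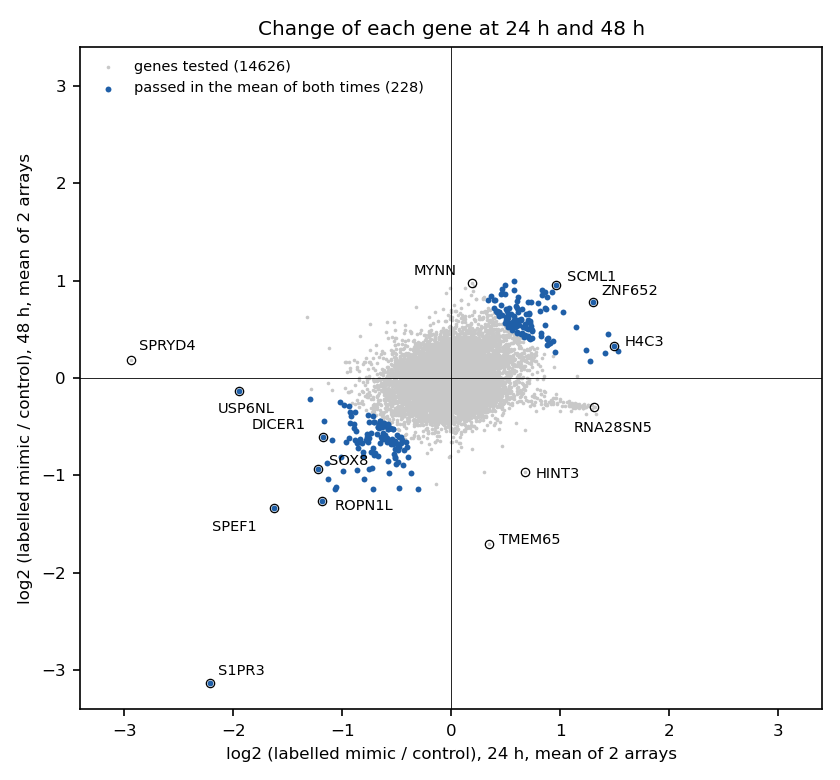
Log2 ratio of RNA labelled mimic over control at 48 h (vertical) against 24 h (horizontal) for 14626 genes, each the mean of 2 arrays, with the 228 genes that passed over both times in blue and named genes circled. S1PR3 lies lowest, at -2.21 and -3.14, and the streak that ends at 28S ribosomal RNA (RNA28SN5) lies above 0 at 24 h and below 0 at 48 h.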

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

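The tests that weigh explanations of the seed match's direction and of the 28S block were chosen after those results were seen, as was leaving out 1 replicate for each difference listed, while the tests of the seed shift itself and of the difference between 48 h and 24 h were planned. The results here are those whose effect differed between the times in the latter test, which passed for 4704 genes. Values are log2 changes at 48 h minus those at 24 h.

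Among the genes with the largest changes at 24 h, the difference was LMNB1 -1.697, RNA28SN5 -1.61, NKX2-5 -1.609, PRR36 -1.604, DUX4 -1.571 and VPS9D1 -1.528. EGF was at -1.259 (resting on replicate 1), H4C3 at -1.158, COX1 at -1.152, TAF15 at -1.09, BPNT1 at -0.9793 and ZNF652 at -0.5184. Those that were lower at 24 h came to SPRYD4 3.124, RAB12 1.943, USP6NL 1.822, ATP7A 1.174 and STXBP5L 1.085. RRAGC stood at 0.7254, DICER1 at 0.5709, SPEF1 at 0.2872 and SOX8 at 0.2868. Of the genes named at 48 h, TMEM65 was at -2.042 (-1.17 without replicate 2), PLA2G2A at -0.9499, S1PR3 at -0.9227 and GRIN3A at -0.8383. NOS3 was at -0.6519, CTXN1 at -0.61 and CD24 at -0.4215. Higher at 48 h than at 24 h were GNB4 0.9331, RIT1 0.7934, MYNN 0.7823, AMTN 0.7326, KIF14 0.6906 and MED18 0.4628, with HPGD 0.4457, HIRA 0.4173 and ACP3 0.3333. Named for the difference alone were HINT3 at -1.641, MAGOH at 1.261 and PRRG1 at 1.429.

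The S phase list had a median difference of -0.2564 (camera adjusted p = 0.020, but 0.99 with an estimated correlation and 0.33 by fry), with MCM5 at -1.138, MCM2 at -0.7209, RRM2 at -0.6013 and CCNE2 at -0.4783. Mitosis genes went both ways: BUB1B -0.55, TPX2 -0.308, CENPE 0.3715 and CENPF 0.465. Androgen response genes were at NDRG1 -0.4683, TRPM8 -0.4036 and ACSL3 -0.2765. Reported targets were at HOXA10 -0.7669, E2F1 -0.2899 and KLF8 -0.2809. The heat shock list did not pass (camera adjusted p = 0.19), but 6 of its 10 genes were lower at 48 h: HSPA8 -0.7178, BAG3 -0.6133, HSPA1B -0.6034, DNAJB1 -0.416, HSPB1 -0.3668 and HSPD1 -0.2866. Of the hypoxia list PFKFB4 was at -0.5846, ENO1 at -0.4407 and ALDOA at -0.4345. Of 27 interferon genes 5 were higher at 48 h than at 24 h and 1 lower (camera adjusted p = 0.34), and those named were IFIT1 0.9212, IFIT2 0.9091, OASL 0.7367 and STAT2 0.394. Of 28 lipid synthesis genes 10 were higher and 5 lower (camera adjusted p = 0.57), and those named were SCD 1.162, SQLE 0.6162, INSIG1 0.6091, HMGCS1 0.5592, FADS1 0.4596, ELOVL6 0.4037 and MSMO1 0.2778.

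Of the p53 list, SESN1 was at 0.7749, BBC3 at 0.5647, PMAIP1 at 0.4717 and TP53I3 at 0.3755. Of the miRNA pathway, AGO4 was at 0.5884, AGO3 at 0.3774 and TARBP2 at -0.3758. Oxidative phosphorylation genes stood at ACADM 0.5733, TFAM 0.534, NDUFA5 0.3796, CYCS 0.3171 and MDH2 -0.5227. Adhesion and mesenchymal genes stood at ITGB1 0.5942, CTNNB1 0.4491, GRHL2 0.4444, ESRP1 0.3912, KRT19 0.3188, VIM 0.3087, JUP -0.4081 and SNAI1 -0.4995. The others were CCND1 -0.6529, PAK4 -0.5109, SMAD1 -0.3729, ID3 -0.3467, ID2 -0.2741, DDC 0.2766, EZR 0.3153, COL1A1 0.3179 and CTTN 0.5963.

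Of these 103 genes 1 turned and 27 became smaller by over 1.5 times without 1 replicate (the value nearest 0 is given). Without replicate 1, EGF was at 0.0079, SPRYD4 at 0.25, CD24 at -0.18, SPEF1 at 0.17, VIM at 0.20, NDUFA5 at 0.15, HIRA at 0.063, HPGD at 0.090 and MED18 at 0.25. Without replicate 2, TMEM65 was at -1.17 (its arrays at 24 h gave -0.53 and 1.21), LMNB1 at -1.13, RIT1 at 0.43, USP6NL at 0.27, BAG3 at -0.38, RRM2 at -0.34, PFKFB4 at -0.39, CCNE2 at -0.21 and TARBP2 at -0.24. Also without replicate 2, SMAD1 was at -0.12, HSPB1 at -0.16, HSPD1 at -0.037, ACSL3 at -0.0047, KRT19 at 0.11, TP53I3 at 0.24, STAT2 at 0.13 and GRHL2 at 0.27. Without replicate 4, ENO1 was at -0.12 and COL1A1 at 0.20.

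Genes with a miR-135a seed match were higher in the RNA labelled mimic, while a mimic is known to lower them. Base composition is argued against, since the shift at 24 h was 0.146 within classes of probe GC, and so is an exchange at 1 time only, since the shift at 48 h was 0.126 with the sign of that at 24 h. An exchange of both RNAs on all 4 arrays, or of the 2 dyes in the labels, and a rise of RNAs with the match in cells given the mimic cannot be told apart. Both need shifts above 0, as found over both times (0.138) and on each array (the lowest was 0.116), which restates the pattern and supports neither, and no mimic level was measured on these arrays. Under an exchange, ROCK1, ESRRA and the genes of dividing cells would be lower, and p53 targets and S1PR3 higher, in cells given the mimic.

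The 45 genes at least doubled at 24 h and below 0 at 48 h include 28S ribosomal RNA. High GC of the probe was not enough alone: all 263 genes with a probe over 60% GC, 31 of the block included, had a median of 0.167 (SD 0.427) at 24 h. The block's median of 1.16 is no test beside it, since its genes were picked for at least doubling. Nor was high GC needed, since 14 genes of the block had a probe of up to 60% GC. A part played by GC stays open, as 31 of the 56 genes at least doubled at 24 h had such a GC-rich probe. A rise of the mRNAs themselves is argued against for the 13 genes other than 28S with another probe above background. Of these, 7.69%, 1 gene, had another probe with a rise of 0.5 times the size or more. Label made from ribosomal RNA that bound to these probes is a candidate explanation. The median of the other probes of these 13 genes was 0.0033 (SD 0.225) at 24 h. Any effect tied to single probes would leave the other probes flat, so this value does not single out ribosomal RNA. For the other genes of the block apart from 28S, which have no other probe above background, both stay open, and no biological explanation was tested.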

How the results depend on the processing

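Leaving out the probes over 60% GC and the seed test within classes of probe GC were chosen after the data were seen, and the other alternatives before. All 228 genes that passed over both times and were tested kept their direction in every alternative run on that test (220 tested with the strict filter and 225 without uneven spots). Leaving out 1 replicate could turn few of them, since 226 had 1 direction on all 4 arrays. The fits with an intensity trend or 4 arrays as replicates leave the log2 change as it is. The number of genes past the threshold moved. It was 11 with no background correction, 450 with the scanner's processed signals, 0 with no filter, 2 with an intensity trend and robust prior, 3 with the deposited value table, 32 with 4 arrays as replicates and 414 without probes over 60% GC, where all 228 still passed; in the other alternatives that kept all arrays it was 180 to 314. With median centring 87 genes passed at 24 h, 4 at 48 h and 4 in the difference, with 5413 of 5784, all 4535 and 4570 of 4704 genes in their direction; the medians of all genes moved to -0.10 at 24 h and 0.11 in the difference, and 155 calls among 207 values of named genes were lost. With no dye term 3271, 1756 and 1581 passed, and with no background correction 7194 in the difference. The other alternatives gave 5002 to 8453 genes at 24 h, 3808 to 6618 at 48 h and 3760 to 6840 in the difference. Without 1 replicate the counts were 1180 to 3425 at 24 h, 341 to 2776 at 48 h, 444 to 2549 in the difference and 0 to 519 over both times, partly by construction, since these fits have no dye term and treat the lone array of a time as varying like the others. The cause of the other changes was not tested.

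Of 19 lists fry called 1 at each time and camera with an estimated correlation 0 at each; without 1 replicate 4 to 6 passed at 24 h and 3 to 7 at 48 h, and in the other alternatives 4 to 9. Camera with an estimated correlation rests on 1 residual degree of freedom, so hardly any list could pass it. Fry rests on the same 1, so its calls depend on 1 residual value per list. At 24 h the stress list was lost with processed signals, with median centring, without replicate 1 and without replicate 3 or 4 (the same fit at 24 h). The miRNA pathway was lost with processed signals and without replicate 1, and the androgen response with median centring. At 48 h the lists of stress, oxidative phosphorylation and reported targets were lost without replicate 3. The 6-base seed shift kept its sign and passed in each alternative run (0.045 to 0.117 at 24 h and 0.036 to 0.080 at 48 h with all arrays; without 1 replicate 0.082 to 0.083 and 0.052 to 0.085), and the correlation between times was 0.132 to 0.289 without 1 replicate. Matching genes on the length or GC content of the 3′ untranslated region and using the shortest one were not run, since those sequences were not at hand.

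Some named values turned: STMN2 at 48 h was 0.015 with no background correction and 0.0071 with median centring, SMAD9 at 24 h was -0.022 with processed signals, and PTPRC at 24 h was 0.081 after Aquantile. With median centring HSPD1 was at -0.022, HSPB1 at -0.053, CLDN7 at -0.044 and STMN2 at 0.13, at 24 h. Ranges without 1 replicate crossed 0 for SMAD1 (-0.0064 to 0.50) and STMN2 (-0.14 to 0.0024) at 24 h, and at 48 h for VIM (-0.15 to 0.032), HSPE1 (-0.085 to 0.54), ENO2 (-0.18 to 0.058) and STMN2 (-0.16 to 0.13). A median signal of 2.74 to 5.95 times the background limits dim genes: 72 at 24 h and 221 at 48 h had neither RNA well above it.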

Other observations

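The cilium tests and their lists were written after SPEF1, ROPN1L, RSPH1 and others were seen to fall but before the values of the lists' genes were looked at; the genes named here were chosen after their values were seen.

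Genes of motile cilia and flagella were lower in the RNA labelled mimic than other genes, in a list of 110 genes that left out the ones noticed first. Of 43 tested, 23 fell and 3 rose at 24 h (median -0.20), and 20 fell and 3 rose at 48 h (median -0.18). The dynein heavy chain DNAH7 was at -0.65 ± 0.09 and -0.67 ± 0.09, LRRC46 at -0.55 and -0.64, DYNLRB2 at -0.67 and -0.51, and CFAP45 at -0.28 and -0.66, while LRRC49 rose (0.20 and 0.67). That only a few noticed genes fell is argued against: among 10000 random lists matched on signal, both medians lay at the 0.01 percentile, the lowest that these lists can give. Whether a smaller fall is shared by the genes of all cilia stays open. Of 71 genes of the primary cilium 24 fell and 9 rose at 24 h, and 17 fell and 9 rose at 48 h, with medians of -0.05 and -0.03 at percentiles of 5.91 and 32.14. A percentile above 5 was to argue against a shared fall, and both percentiles lay above it, that at 24 h narrowly. More of these genes fell than rose at both times, so the rule does not exclude a smaller fall in them. Their SD across genes was 0.26 and 0.24, which is not the uncertainty of a median. That a programme of motile cilium genes may be lower in the RNA labelled mimic (higher in cells given the mimic, if the RNAs were exchanged) is a hypothesis found and tested on the same arrays.

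Among genes with the 7-base seed match, the carrier of ADP and ATP SLC25A5 was at 0.54 at 24 h and 0.46 at 48 h, the mitochondrial peptidase subunit IMMP1L at 0.59 and 0.42, the helicase MCM8 at 0.51 and 0.32, and the metalloreductase STEAP2 at 0.51 and 0.24. None of the 4 passed over both times (adjusted p = 0.065, 0.065, 0.14 and 0.22). DYNC2LI1 had the match and fell at 24 h (-0.49), with -0.12 at 48 h.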
